A study of Drosophila melanogaster with 3 samples.

How the data were processed

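Gene expression was measured by RNA sequencing in salivary glands of third-instar (L3) larvae of Drosophila melanogaster. Per the labels' protocols, each sample pooled 50 dissected glands, TRIZOL served for RNA extraction, and libraries of poly(A) RNA were made with a directional kit. The 3 libraries form 1 group of control glands, named replicates 1, 2 and 3 as in the sample titles. The titles name an Oregon stock while the genotype field reads yw, and this difference was left open. Nothing in the labels says whether the 3 samples came from separate cultures or animals, so the spread between them may be technical and p-values over libraries measure only that spread.

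The deposited values are FPKM, fragments scaled by the authors to gene length and library depth, with 1 value per gene and library for 17278 FlyBase gene identifiers. HISAT2 and DESeq are named in the submitters' processing notes without versions. The genome build, the gene annotation, the counting program and the fragments taken as library depth are not given in the sources used here. The kit marks strand, but the name of the deposited table marks the counting as unstranded. A gene and its antisense or overlapping partner are therefore uncertain, and so are near-identical copies such as the replication-dependent histones and the rRNA pseudogenes.

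Identifiers were matched to Ensembl BDGP6.54, release 115, which held 17142 of them and lacked 136. Coordinates are from that build. Each FPKM value was multiplied by the summed length of the gene's annotated exons. The products were whole multiples of 1 step per library, within 0.01 of a whole number, for 98.7% to 98.8% of values above 0, so that fragments per gene could be recovered. They served to describe depth, intervals and limits, and no count model was fitted. Recovered totals were 1509433, 1490262 and 1571526 fragments in replicates 1, 2 and 3, of which 678717, 874009 and 1185543 lay outside rRNA pseudogenes. The step sizes correspond to denominators of 499875, 727436 and 945562 fragments, smaller than these totals. A single fragment in a gene of 2000 bases equals 1.0, 0.687 and 0.529 FPKM. A limit of 1 FPKM therefore rests on 1 fragment for many short genes. Wilson intervals of 95% were used for shares and exact intervals for ratios of fragments. A count of 0 was taken to allow up to 3 fragments. Intervals and limits cover counting error only.

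Levels were compared as log2(FPKM + 1), with a pseudocount of 1, so ratios of low genes are understated. A gene counted as detected at 1 FPKM or more in every library. The study's series title names the H3K9 methyltransferases SetDB1 (gene egg) and Su(var)3-9, and the 3 pairs formed with G9a were compared within libraries by a two-sided exact sign-flip permutation test, whose smallest p with 3 libraries is 0.25. Before the data were examined, 28 gene lists were fixed. Each list's median of mean log2(FPKM + 1) was set against all other genes by a two-sided permutation test with 100000 random lists of the same size, with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. The smallest adjusted p that the test gave was 7e-05, which stands for the smallest p that the permutations can give. This test resamples genes, which are not independent replicates, and describes these libraries. Chromosome 4 and pericentromeric lists were compared by 100000 reassignments of their members. Differences of lists between libraries were described as the median deviation of members from their own mean over the libraries, without a test.

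The genes named were fixed by a rule: all members of the glue list and of the H3K9 list, the 20 highest genes, the 4 highest and 2 lowest members of every other list, and the 10 genes with the largest SD of log2(FPKM + 1) among those with a mean of at least 10 FPKM. Other named genes were chosen after their values were seen. These are further members of the fixed lists, genes beside the glue genes, the Eig71E genes, a second list of ecdysone-inducible genes, and structural RNAs. List members absent from the annotation under the listed name were left out, among them sov in the H3K9 list.

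The list test was tested on simulated lists of 15 genes drawn from the 17278 genes. Of 100 lists per level, 4% passed an unadjusted p of 0.05 with no added level, 15% with 1 added log2 unit, 35% with 2 and 100% with 3. Members were drawn at random, so the share with no added level was set by the design of the test. Lists of related genes and other list sizes were not simulated. The alternatives were other detection limits, pseudocounts of 0.1 and 0.01, no pseudocount, rescaling to an equal sum per library (TPM) or by median ratios, other backgrounds, the mean in place of the median, and each library left out in turn. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and intervaltree 3.1.0.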

Results

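The salivary glands of L3 larvae, a secretory tissue with polytene chromosomes, were profiled in 3 libraries of 1 control group. The series title concerns the H3K9 methyltransferases SetDB1, encoded by egg, and Su(var)3-9. With a single group, the data describe levels within this tissue and the spread between its libraries. Depth outside rRNA pseudogenes was 678717 fragments in replicate 1, 874009 in replicate 2 and 1185543 in replicate 3.

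Genes of the glue proteins, which the gland secretes to fix the pupa to a surface, had the 6 highest protein-coding levels. Sgs7 stood at 311039 ± 52891 FPKM (SD, n = 3), Sgs3 at 199524 ± 39418, Sgs5 at 134171 ± 21188 and Sgs8 at 129245 ± 26544. Sgs4 followed at 68518 ± 6879 and Eig71Ee at 35081 ± 3378. Sgs5bis, at 12853 ± 1334, and Sgs1, at 5760 ± 1688, lay below genes outside the glue list. Glue genes took 65.3% ± 3.57 (SD, n = 3) of the summed FPKM without rRNA pseudogenes, and 43.8% ± 7.61 with them. The 10 highest genes, rRNA pseudogenes included, took 67.6% ± 4.51. Summed FPKM gives short genes more weight than fragments do. By recovered fragments outside rRNA pseudogenes, glue genes held 50.85%, 43.9% and 47.23% in replicates 1, 2 and 3.

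Outside the glue list, the 20 highest genes included CG12310 at 22355 ± 6432 FPKM, the translation elongation factor gene eEF1alpha1 at 7956 ± 1374, CG15404 at 6709 ± 1498, CG31698 at 6443 ± 1252 and RpL41 at 6357 ± 2492 (SD, n = 3). The others were 8 rRNA pseudogenes, led by 28SrRNA-Psi:CR45860 at 153560 ± 102163. rRNA pseudogenes held 55.0% of recovered fragments in replicate 1 (95% Wilson interval 55.0% to 55.1%), 41.4% in replicate 2 (41.3% to 41.4%) and 24.6% in replicate 3 (24.5% to 24.6%). Their copies are nearly identical, so levels of single copies are uncertain.

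The glue list as a whole lay above other genes by 14.0 on the log2(FPKM + 1) scale (12 members, adjusted p = 7e-05, permutation test), in each of the 3 libraries. The new glue genes on the X chromosome differed between libraries. ng1 had 38.3, 76.2 and 1157 FPKM in replicates 1, 2 and 3, ng2 had 253, 244 and 2003, and ng3 had 3159, 1597 and 8685. In the same libraries, the fat body list deviated from its mean by -0.40, -0.015 and 0.482, the mitochondrial list by -0.50, 0.03 and 0.53, and the rRNA pseudogene share was 55.0%, 41.4% and 24.6%. ng4 rested on 1 fragment in replicate 2.

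**Figure D1:**
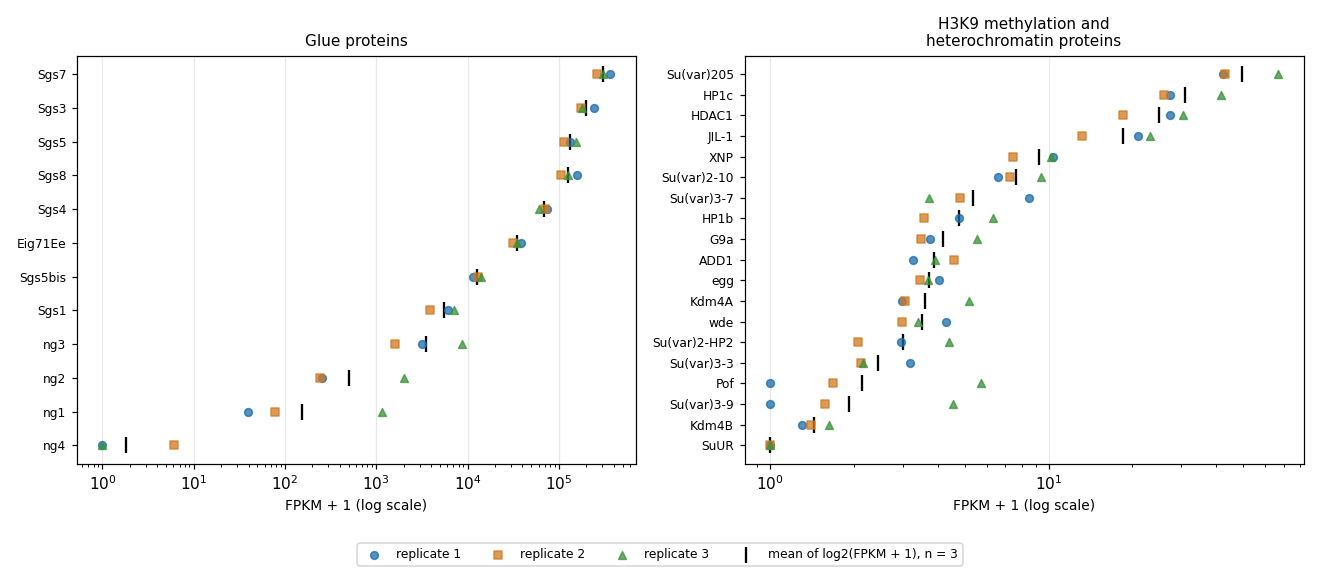
FPKM + 1 on a log axis for each glue gene (left) and each gene of H3K9 methylation and heterochromatin (right). Points are the 3 libraries and black ticks the mean of log2(FPKM + 1). Sgs7 was highest at a mean of 311039 FPKM, whereas egg had a mean of 2.73 FPKM.

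The next comparison concerns the methyltransferases of the title and their partners. egg (FBgn0086908, BDGP6.54 2R 24775534 to 24779901) had 3.05, 2.44 and 2.69 FPKM in replicates 1, 2 and 3, with a mean of 2.73 ± 0.304 (SD, n = 3) from 23 fragments. Its binding partner gene wde had 2.56 ± 0.672. G9a (FBgn0040372, X 245978 to 254650), the other H3K9 methyltransferase gene, had 3.26 ± 1.11 from 54 fragments. Su(var)3-9 (FBgn0263755, 3R 15259864 to 15263458) was listed at 0 in replicate 1, where a count of 0 allows up to 2.52 FPKM, at 0.576 in replicate 2 and at 3.55 in replicate 3, from 9 fragments in all.

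With 3 libraries, no pair could pass the exact sign-flip test. egg exceeded Su(var)3-9 by 0.95 ± 1.17 on the log2(FPKM + 1) scale (SD, n = 3), higher in 2 of 3 libraries (exact sign-flip p = 0.5). Per exon base, the ratio of fragments was 1.55 (95% exact interval 0.69 to 3.8). The difference was 0.41 without replicate 1, 1.57 without replicate 3, and 2.17 and 3.31 with pseudocounts of 0.1 and 0.01. egg minus G9a was -0.16 ± 0.37 (exact sign-flip p = 0.75, n = 3), with a ratio of 0.783 (0.458 to 1.3), and became -0.298 without replicate 1 and 0.047 without replicate 3. G9a exceeded Su(var)3-9 by 1.11 ± 0.82, more than the SD, in 3 of 3 libraries (exact sign-flip p = 0.25, the smallest possible with n = 3), with a ratio of 1.98 (0.969 to 4.56). It was 0.71 without replicate 1, and 2.37 and 3.52 with the smaller pseudocounts. The adjusted p was 0.75 for each pair. Differences within these intervals were not detectable at this depth. Su(var)3-9 shared 14.8% of its exon bases with eIF2gamma on the same strand, and egg 16.0% with an antisense RNA. G9a shared none. If fragments in shared bases were left out of the counts, the ratios per exon base would lean toward G9a.

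Among the other chromatin genes, Su(var)205, which encodes the heterochromatin protein HP1a, had the highest level at 49.8 ± 13.9 FPKM (SD, n = 3). HP1c had 30.7 ± 8.70, the deacetylase gene HDAC1 24.4 ± 6.19, and JIL-1, which encodes a histone H3 kinase, 18.1 ± 5.21. XNP had 8.36 ± 1.66, Su(var)2-10 6.74 ± 1.48, Su(var)3-7 4.69 ± 2.52 and HP1b 3.88 ± 1.36. ADD1 (2.92 ± 0.648), the demethylase gene Kdm4A (2.73 ± 1.26), Su(var)2-HP2 (2.14 ± 1.17) and Su(var)3-3 (1.48 ± 0.600) were lower. Pof, which encodes a chromosome 4 binding protein, had 0, 0.685 and 4.74 FPKM in replicates 1, 2 and 3. Kdm4B, at 0.444 ± 0.168, shared 84.8% of its exon bases with other genes. SuUR was listed at 0, and all of its exon bases lay in exons of another annotated gene, so its level is not known.

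Of the 19 matched genes of this list, 15 were detected in every library. The list lay 1.58 above other genes on the log2 scale without passing the test (adjusted p = 0.136, permutation test). Against genes of at least 1 FPKM on average, the sign turned. The difference was -1.08 for the 17 members kept, again without passing (adjusted p = 0.0809, permutation test). Against all other genes, Polycomb group genes (15 members, 2.15, adjusted p = 0.0955) and trithorax group genes (9 members, 2.38, adjusted p = 0.151) did not pass the permutation test either. Their signs also turned against genes of at least 1 FPKM on average. The differences there were -0.61 for Polycomb (adjusted p = 0.372) and -0.38 for trithorax genes (adjusted p = 0.595, permutation tests). Caf1-55 led the former at 37.7 ± 1.65 FPKM, and kis (21.7 ± 5.46) and osa (20.6 ± 8.47) the latter (SD, n = 3).

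Genes of dosage compensation did not stand apart (8 members, 1.64, adjusted p = 0.33, permutation test). Against genes of at least 1 FPKM on average, the difference was -0.57 for the 6 members kept (adjusted p = 0.519, permutation test). Clamp had 20.1 ± 3.64 FPKM, mle 6.56 ± 1.39 and msl-1 5.78 ± 0.447 (SD, n = 3). Both roX RNAs, components of the male dosage compensation complex, were listed at 0 in every library. Counts of 0 allow up to 1.1, 0.754 and 0.58 FPKM for roX1 and 4.39, 3.01 and 2.32 FPKM for roX2 in replicates 1, 2 and 3. Germline and piRNA pathway genes also did not stand apart (17 members, -0.15, adjusted p = 0.695, permutation test). Only tud, at 38.5 ± 2.72 FPKM, was detected in every library, while piwi, vas and rhi were listed at 0.

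Chromosome 4 and the pericentromeric regions are chromosome parts known for SetDB1 and Su(var)3-9. The fixed lists of genes from both parts lay above other genes. The difference was 2.54 for the chromosome 4 list (52 members, adjusted p = 7e-05, permutation test). It was 2.95 for the pericentromeric list (22 members, adjusted p = 0.00162, permutation test). The lists do not cover all genes of these parts. On chromosome 4, RpS3A had 2020 ± 410 FPKM, the GTPase gene Arf4 207 ± 82.2, ATPsynbeta 130 ± 50.9 and CaMKI 53.8 ± 14.2, while onecut and Actbeta were listed at 0 (SD, n = 3). Among pericentromeric genes, RpL15 had 1480 ± 132, RpL5 677 ± 42.6, RpL38 404 ± 128 and Yeti 54.6 ± 9.01, while spok and Myo81F were listed at 0. The median member had 7.17 FPKM on chromosome 4 and 9.49 FPKM in the pericentromeric list.

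The lists did not differ by the test. Chromosome 4 minus pericentromeric was -0.41 on the log2 scale (p = 0.526, permutation test), and -0.49 ± 0.22 per library (SD, n = 3), below 0 in all 3. With only members of at least 1 FPKM on average it was 0.45 (p = 0.354, permutation test). Against a background of genes with at least 1 FPKM on average, the pericentromeric list no longer passed (0.53, adjusted p = 0.379), while chromosome 4 did (0.98, adjusted p = 0.0299, permutation tests).

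Genes of gland identity, secretion and protein synthesis were high in this tissue. The identity list lay 5.45 above other genes (12 members), secretory pathway genes 7.46 (20 members) and cytosolic ribosomal protein genes 10.3 (84 members), each with an adjusted p of 7e-05 by the permutation test. The transcription factor genes sage and CrebA had 723 ± 52.0 and 127 ± 70.9 FPKM, the glycosyltransferase gene Pgant9 had 243 ± 15.1 and PH4alphaSG2 79.6 ± 28.4 (SD, n = 3). At the low end, Pgant4 had 1.77 ± 1.61 and hth 0.826 ± 0.316. All 20 secretory genes were detected in every library, from Sec63 at 40.6 ± 12.7 to Hsc70-3, which encodes the chaperone BiP, at 1133 ± 274. Calr had 735 ± 264, KdelR 661 ± 291 and Sec61beta 613 ± 307. RpL27A (3969 ± 363), RpL23 (3767 ± 332) and RpS18 (3523 ± 349) followed RpL41, whereas RpS10a and RpS28a were listed at 0.

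Respiratory chain genes of the nucleus (28 members, 5.94) and of mitochondrial DNA (13 members, 7.74) were above other genes, each with an adjusted p of 7e-05 by the permutation test. levy had 208 ± 34.5 FPKM, COX7A 197 ± 26.8 and blw 178 ± 36.6 (SD, n = 3). Mitochondrial mt:CoIII had 2293 ± 885, mt:CoI 1483 ± 512, mt:Cyt-b 1206 ± 385 and mt:CoII 925 ± 327. The mitochondrial list deviated by -0.50, 0.03 and 0.53 from its mean in replicates 1, 2 and 3, a range of 1.03, and by -0.89, 0.07 and 0.81 as TPM, a range of 1.69. The sums used for TPM include the rRNA pseudogenes. TPM also widened the range of the ribosomal protein list, from 0.0373 to 0.601, so the wider range is not particular to mitochondrial genes. The rRNA pseudogene share was 55.0%, 41.4% and 24.6% in these libraries.

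Ecdysone, the steroid hormone that times metamorphosis, acts through EcR and usp. The ecdysone response list was above other genes by 3.70 on the log2 scale (15 members, adjusted p = 0.00118), and by 2.64 without replicate 2, where it no longer passed (adjusted p = 0.0503, permutation tests). Eip74EF had 74.8 ± 32.5 FPKM, br 70.9 ± 28.3, EcR 40.9 ± 11.5 and usp 33.0 ± 7.27 (SD, n = 3). Several members differed between libraries. Eip78C had 39.1, 119 and 0.18 FPKM in replicates 1, 2 and 3, Hr4 had 12.5, 20.9 and 0.0761, and Eip75B had 44.8, 62.2 and 8.26. The list deviated from its mean by 0.23, 0.23 and -0.42 in replicates 1, 2 and 3, a range of 0.65. As TPM it deviated by 0.00, 0.27 and -0.15 (range 0.42), and with members of at least 20 fragments by 0.42, 0.45 and -0.73 (range 1.18). In the same libraries, the fat body list deviated by -0.40, -0.015 and 0.482, the mitochondrial list by -0.50, 0.03 and 0.53, and the rRNA pseudogene share was 55.0%, 41.4% and 24.6%. Heat shock genes deviated by 0.14, 0.13 and -0.23, or by 0.33, 0.99 and -1.31 with members of at least 20 fragments. Antimicrobial peptide genes, which rest on few fragments, deviated by 0.795, 0.00 and -0.67. Hr38 and Hr3 were listed at 0, and Hr3 shared 82.7% of its exon bases with other genes.

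**Figure D2:**
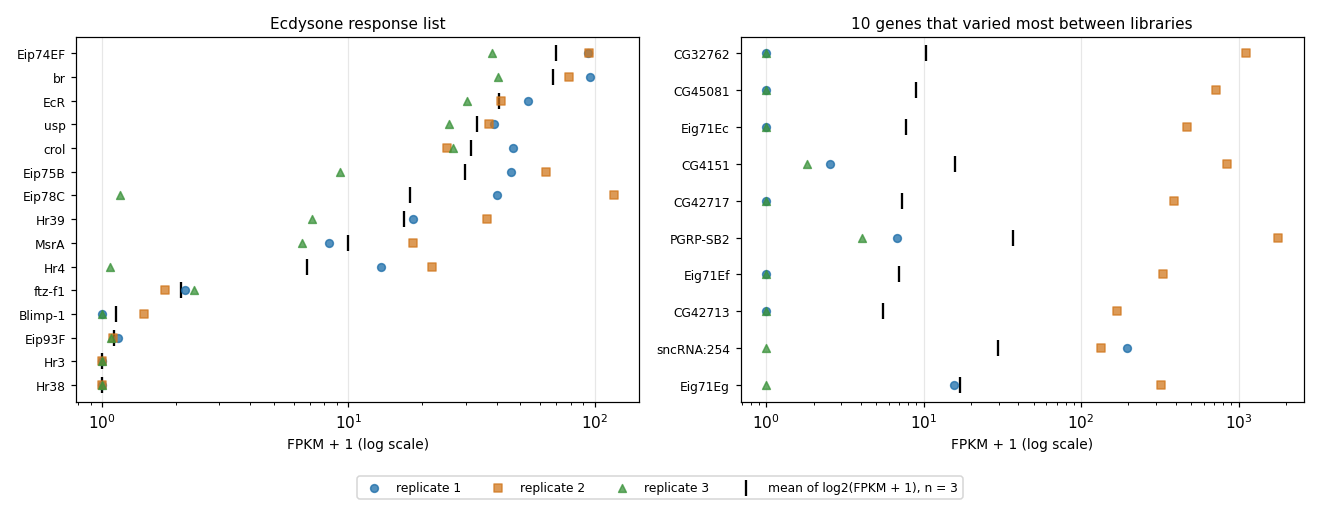
FPKM + 1 on a log axis for the ecdysone response list (left) and for the 10 genes with the largest SD between libraries among genes of at least 10 FPKM on average (right). Points are the 3 libraries and black ticks the mean of log2(FPKM + 1). Eip78C had 119 FPKM in replicate 2 and 0.18 in replicate 3, and CG32762 was above 0 only in replicate 2, at 1114.

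Cell death and autophagy genes passed the test (12 members, 3.19, adjusted p = 0.0128, permutation test), but not against genes of at least 1 FPKM on average (11 members kept, 0.45, adjusted p = 0.519). Atg8a had 169 ± 39.8 FPKM, the caspase inhibitor gene Diap1 87.3 ± 26.2, Atg18a 30.9 ± 3.63 and Atg7 18.3 ± 11.0 (SD, n = 3). hid had 1.15 ± 1.20, and grim, listed at 0, shared 75.9% of its exon bases with other genes.

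The gland's nuclei endoreplicate and do not divide. Replication and endocycle genes did not pass the test (16 members, 2.06, adjusted p = 0.0902), nor did mitosis genes (15 members, 0.48, adjusted p = 0.555, permutation tests). RnrS had 26.2 ± 9.65 FPKM, E2f1 18.9 ± 4.40 and PCNA 11.2 ± 4.84, whereas Bub1, the highest mitosis gene, had 5.93 ± 0.147 and CycA 1.88 ± 0.410 (SD, n = 3). Against genes of at least 1 FPKM on average, the 8 mitosis genes kept lay below the others, with a difference of -1.84 on the log2 scale (adjusted p = 0.012, permutation test). There the 14 replication and endocycle genes kept differed by -0.41 without passing (adjusted p = 0.519, permutation test). Of 111 replication-dependent histone genes, 110 were listed at 0 (-0.39, adjusted p = 0.136, permutation test). The list passed as lower among protein-coding genes (-0.75, adjusted p = 0.00042, permutation test) and with the mean in place of the median. The near-identical copies of these genes make their values uncertain, and histone mRNAs lack poly(A) tails.

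Fat body is the storage tissue next to the glands. Among the lists of markers of other tissues, only that of fat body passed the test against all other genes. It lay 8.37 above other genes (9 members, adjusted p = 7e-05, permutation test). Fbp1 had 926 ± 606 FPKM, Lsp1gamma 895 ± 396, Fbp2 724 ± 165 and Lsp1beta 610 ± 203, against FASN1 at 4.20 ± 1.71 (SD, n = 3). Adh rested on 1 fragment and shared 93.9% of its exon bases with other genes. Fbp1 had 1037, 1468 and 272 FPKM in replicates 1, 2 and 3, and Lsp1alpha had 270, 298 and 979. The list deviated from its mean by -0.40, -0.015 and 0.482, a range of 0.883, and by -0.80, 0.07 and 0.61 as TPM, a range of 1.41. TPM also widened the ribosomal protein list, to a range of 0.601.

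The lists for hemocytes (0.43, adjusted p = 0.6), muscle (0.63, adjusted p = 0.555), cuticle and trachea (0.86, adjusted p = 0.543), imaginal discs (0.19, adjusted p = 0.834), midgut (-0.37, adjusted p = 0.525), nervous system (-0.34, adjusted p = 0.6) and testis (-0.38, adjusted p = 0.555) did not pass the permutation test. In the order first given, the highest members of the lists were crq at 16.8 ± 8.68 FPKM, TpnC73F at 25.7 ± 12.4, pio at 6.72 ± 1.78, ct at 8.94 ± 2.02, Jon99Cii at 0.774 ± 1.34, Syt1 at 1.66 ± 0.504 and mia at 1.32 ± 0.435 (SD, n = 3). Jon99Cii rested on 1 fragment. For hemocytes, muscle, and cuticle and trachea, the sign turned against genes of at least 1 FPKM on average. The 5 hemocyte genes kept lay below the others there (-1.99, adjusted p = 0.0299, permutation test). The 6 muscle genes kept did not pass there (-0.98, adjusted p = 0.32, permutation test). Nor did the 6 cuticle and trachea genes kept (-1.03, adjusted p = 0.304, permutation test). With the mean in place of the median, the midgut (-1.35), testis (-1.33), neural (-1.19), germline (-1.02) and histone (-1.51) lists lay below other genes past the threshold. The mean and median of the mitosis, hemocyte, muscle, cuticle and disc lists differed in sign, and neither passed.

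Heat shock genes (15 members, 0.64, adjusted p = 0.525) and antimicrobial peptide genes (14 members, 0.80, adjusted p = 0.518) did not pass the permutation test. For antimicrobial peptide genes, the sign turned against genes of at least 1 FPKM on average. The 10 members kept lay below the others there (-1.55, adjusted p = 0.0299, permutation test). The 8 heat shock genes kept did not pass there either (1.23, adjusted p = 0.206, permutation test). Hsc70-4 had 343 ± 46.1 FPKM, Hsp27 168 ± 110 and Hsp83 90.5 ± 40.5 (SD, n = 3). Hsp23 had 380, 672 and 37.1 FPKM in replicates 1, 2 and 3. Hsp70Aa was listed at 0, and so was Hsp22, whose exon bases all lay in exons of another gene. CecC had 72.6, 32.1 and 8.22 FPKM in replicates 1, 2 and 3, from 26 fragments, and DptB 49.0, 18.4 and 21.2. The heat shock list deviated from its mean by 0.14, 0.13 and -0.23, a range of 0.37 that was 0.21 as TPM and 2.30 with members of at least 20 fragments. As deposited, the antimicrobial peptide list deviated by 0.795, 0.00 and -0.67, the largest range of all lists at 1.47. As TPM its range was 0.77, below that of others such as the mitochondrial list at 1.69. The list rests on few fragments and had too few members with at least 20 to be kept in that setting.

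**Figure D3:**
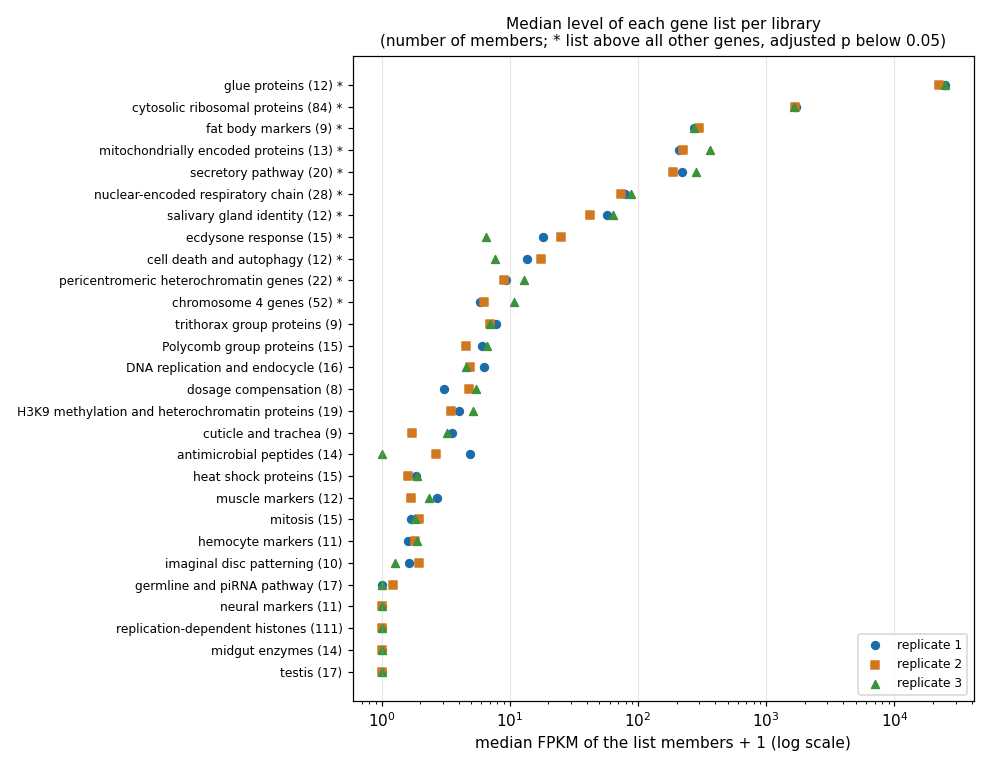
Median FPKM + 1 of the members of each of the 28 gene lists on a log axis, with 1 point per library and the number of members in parentheses. Lists with an asterisk lay above all other genes at an adjusted p under 0.05. Glue proteins were highest, at 14.0 above other genes on the log2 scale, and 11 of the 28 lists passed.

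In all, 11 lists lay above other genes and none below, while 17 did not pass. The median gene of the background stood at only 0.37 on the log2(FPKM + 1) scale, which leaves little room below it. Against genes of at least 1 FPKM on average, 22 lists could be tested, of which 9 were higher and 3 lower. The germline, histone, midgut, neural, imaginal disc and testis lists kept at most 2 members there and were not tested.

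Across the genome, 5711 genes reached 1 FPKM in every library, and 6739, 7267 and 6888 did so in replicates 1, 2 and 3. The median SD of log2(FPKM + 1) over detected genes was 0.39. Among all genes, detected or not, the median SD was 0.60 for genes with 3 to 10 fragments and 0.29 for those with 1000 or more. Across all genes, which are not independent replicates, Pearson correlations were 0.941 for replicates 1 and 2, 0.938 for 1 and 3, and 0.922 for 2 and 3, and Spearman correlations were 0.858, 0.869 and 0.853. Genes more than 2-fold apart numbered 638, 1052 and 1221 of the 5711 in the same pairs.

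The 10 genes that varied most between libraries were almost all high in replicate 2. CG32762 had 1114 FPKM there and 0 in both other libraries. PGRP-SB2, of the peptidoglycan recognition protein family, had 5.82, 1778 and 3.07 FPKM in replicates 1, 2 and 3, and CG4151 had 1.53, 846 and 0.809. CG45081 (720), Eig71Ec (469), CG42717 (391), Eig71Ef (331) and CG42713 (167) were above 0 only in replicate 2. Eig71Eg had 14.5, 320 and 0 FPKM. The exception, sncRNA:254, rested on 6 fragments.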

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

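Several tests were chosen after seeing the data. These were the tests on protein-coding genes, on genes with at least 3 or 20 recovered fragments and without rRNA pseudogenes. The same holds for named genes rescaled by median ratios, both ecdysone lists against matched lists, and the 20 lists named below. Median-ratio factors were 1.012, 0.972 and 1.035 in replicates 1, 2 and 3, so this rescaling could move values only a little. It left all 233 named genes within 1 SD. Detected genes fell to 3628 at 5 FPKM, against 5711. The median SD of 0.39 became 0.44 and 0.45 with pseudocounts of 0.1 and 0.01, 0.47 without a filter, 0.46 as TPM, 0.33 with at least 20 fragments in every library, and 0.27 to 0.35 with a library left out. The egg and G9a difference ranged from -0.298 to 0.047 with a library left out and was above 0 only without replicate 3. Chromosome 4 against pericentromeric genes turned to 0.45 with members of at least 1 FPKM. The cause was not tested. The median range of list deviations between libraries was 0.49 as TPM against 0.36, and 0.56 with members of at least 20 fragments, which 20 lists kept, against 0.41 for these 20 lists with all members. The 50 highest genes held 83.7% of summed FPKM. With genes of at least 1 FPKM on average, the mitosis (-1.84, 8 members kept), antimicrobial peptide (-1.55, 10 members) and hemocyte (-1.99, 5 members) lists lay below other genes. That background has a higher median. Pseudocounts and TPM changed no list's call. Leaving out replicate 1 or 3 changed none, and leaving out replicate 2 ended that of the ecdysone list. With the background limited to protein-coding genes, the histone list passed as lower (adjusted p = 0.00042, permutation test), as it did with the mean in place of the median. Without a pseudocount, both pairs with Su(var)3-9 gave no value, because replicate 1 is at 0. Few fragments limit the methyltransferase pairs, and no exact test with 3 libraries can pass 0.05. No paired analysis was possible because there is 1 group, so that no groups share replicate numbers; pairs of genes were compared within libraries.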

Other observations

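Each test in this part was chosen after the result it follows had been seen. Single genes beside glue genes were abundant. CG14265 had 4990 ± 1902 FPKM, CG7606 3263 ± 350 and Pig1, next to Sgs4, 1582 ± 412 (SD, n = 3). Over the 41 protein-coding genes within 20 kb of a glue gene, glue genes left out, 29.3% reached 100 FPKM, against 3.31% of other protein-coding genes, and their median was 4.92 FPKM. The share was 14.6% without replicate 2 and 19.4% without the Eig71E genes. Their median lay 1.55 higher on the log2 scale (p = 0.0354, permutation test). Without replicate 2 the difference was 0.89 (p = 0.203), and without the Eig71E genes it was 1.20 (p = 0.148, permutation tests), so whether the neighbourhood as a whole is raised stayed open.

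Of the 79 protein-coding genes of chromosome 4, 52 belong to the chromosome 4 list. The other 27 had a median of 2.11 FPKM and lay 0.898 above protein-coding genes of the other arms on the log2 scale (p = 0.294, permutation test), so whether the higher level of the list extends to the rest of the chromosome stayed open. With the list included, 55.7% of chromosome 4 genes were detected in every library, against 37.4% to 43.2% on the X and the arms of chromosomes 2 and 3.

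Hormone-response genes such as Eip78C differed between the 3 libraries. A candidate explanation is that the libraries were taken at different times relative to the ecdysone pulse. Over replicates 1, 2 and 3, fat body markers deviated by -0.40, -0.015 and 0.482. Antimicrobial peptide genes, which rest on few fragments, deviated by 0.795, 0.00 and -0.67. Heat shock genes of at least 20 fragments deviated by 0.328, 0.987 and -1.31. A second list of 12 ecdysone-inducible genes was not among the lists fixed before the data were examined. Of its members, 8 were lowest in replicate 3, such as Sox14 at 64.3, 124 and 9.46 FPKM and E23 at 15.2, 25.9 and 2.26. Cth ran the other way, at 69.0, 47.4 and 103.8 FPKM, and some members rested on few fragments, such as 1 for Cyp18a1 and 2 for ImpE3. Relative to 10000 lists matched on mean level, the list deviated by 0.548, 0.212 and -0.395 in replicates 1, 2 and 3. This range of 0.942 lay at percentile 99.9 of these lists (0.717 at percentile 99.4 as TPM). The matched lists hold random genes, and percentiles were taken only for the ecdysone lists. As deposited and without matching, the mitochondrial list ranged by 1.03 and the fat body list by 0.883. The median range of the 28 lists was 0.36. The percentile therefore does not show that the movement was particular to ecdysone genes. Different times would give the range of the second list, and so might any other difference that moves its genes. This form of the test was the third and was chosen after the results of 2 others had been seen: a comparison of replicate 3 with the other 2, dropped because it grouped libraries by a measured outcome, and the range of 0.913 of the list alone, at percentile 99.8 as deposited but at 19.6 as TPM, which moved the matched lists themselves by -0.282, 0.10 and 0.16. The first ecdysone list was also set against matched lists, to look at scaling of the libraries alone. It had itself raised the question, so its high percentile cannot argue against scaling. A factor per library moves matched lists alike, and this list deviated from them with a range of 0.649, at percentile 99.9 (0.525 at percentile 99.2 as TPM). This test was chosen after the results of 2 other forms had been seen. An earlier form compared the new glue genes with this list and was dropped. Another used the spread among this list's members, a mean SD of 0.791, which reached only percentile 95.3 (94.2 as TPM) and could not tell. A larger amount of fat body in replicate 2 was argued against as the source of the Eig71E genes. From replicate 1 to replicate 2, the median change of fat body markers differed from theirs by -4.4 (Eig71Ea had 24.3 and 1094 FPKM, apolpp 9.18 and 17.4, FASN1 3.89 and 2.67). The markers track only the amount of fat body, so a change of the Eig71E genes within it was not tested. Hemocytes as the source of the Eig71E genes stay open, because only 3 of 11 markers had at least 20 fragments. Their difference of -4.9 is therefore uninformative (crq had 9.83 and 26.5 FPKM). A difference in age also stays open, since staging was not recorded beyond L3.

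The share of rRNA pseudogenes also differed between the libraries, and RNA without poly(A) tails may have been removed less completely in some of them. The 7SL, 7SK, RNase MRP and RNase P RNAs, which lack such tails, made 684, 170 and 67.5 per 1000000 of the fragments outside rRNA pseudogenes in replicates 1, 2 and 3. Replicate 1 exceeded replicate 3 by a ratio of 10.1 (95% exact interval 7.98 to 13.0). rRNA pseudogenes held 830716, 616253 and 385983 fragments in replicates 1, 2 and 3, against 678717, 874009 and 1185543 outside them. Relative to the fragments outside, they fell by less than the structural RNAs, so both classes did not change in proportion. Some values of the structural RNAs had been seen when the test was chosen, and no biological explanation was tested.

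Several well-known genes were listed at 0 while their exons lay in other genes, and fragments in exons of 2 genes may have been left out of the counts. Of 377 protein-coding genes with all exon bases in exons of other genes of the table, 377 were at 0 in all 3 libraries. Of 592 genes with at least 75% shared, 90.4% were at 0, against 31.8% of 11030 genes with at most 5% shared (p = 3.6e-186, Fisher's exact test). Where every partner lay on the opposite strand the share was 83.4% of 175 genes, 2.62 times that of genes with at most 5% (p = 1.9e-44, Fisher's exact test), as unstranded counting would give. Some rRNA pseudogenes inside a longer annotated precursor had high values, but that precursor is not among the genes of the table; a value of 0 for SuUR or Hsp22 may therefore say nothing about expression, and for Hr3 and grim it may rest on their unshared exon bases.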
